A study of Homo sapiens with 18 samples.

How the data were processed

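RNA and surface antibody tags of bone marrow mononuclear cells were measured by droplet sequencing (CITE-seq) in 18 libraries, 1 per donor: 4 healthy, 7 MGUS and 7 WM. For each library the authors deposited an unfiltered matrix of raw UMI counts, with 36601 genes and 53 antibody tags as features and 737280 barcodes. The labels name Cell Ranger 4.0 and Seurat 3 and a GRCh38 (hg38) reference, without order or options. The deposited values are counts per the file headers, with no normalization. Replicate numbers repeat across groups, but the donors differ, so libraries were treated as unpaired. The gene lists, markers, filters, tests and most alternatives were fixed before the data were examined.

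Gene IDs were matched to GENCODE 29 (GRCh38) for coordinates and chromosomes: 34508 matched. To protect donors, 108 genes that could point to a donor's sex were left out of every table, which left 36493 genes, and 2 light chain tags were left out of the protein tests, which left 51. Antibody V, D and J segments and T cell receptor segments stayed in the gene tests and were counted but not named.

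Barcodes with at least 500 gene UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept as cells. The mitochondrial filter removed 1.10% to 15.8% of the barcodes that passed the others. Cells held 85.4% to 96.7% of a library's gene UMIs and 14.0% to 71.9% of its antibody counts. Doublets were scored per library with a nearest-neighbour method on simulated doublets (as in Scrublet), and the highest scores were left out at 0.8% per 1000 cells, 2.75% to 6.55% of a library. The most that any pair of libraries shared of their cell barcodes was 1.37%.

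All cells were clustered together in Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9, using 2000 variable genes (without antibody, T cell receptor, ribosomal and mitochondrial genes), 30 principal components, 15 nearest neighbours and Leiden resolution 1.5, without alignment of libraries. This gave 41 clusters. A cluster took a class name when no other class had more of the fixed markers among its 10 leading genes and at least 3 of the class's own markers were detected. Several named clusters had 0 of their class's markers among the 10 leading genes, so these genes alone do not settle their names. Among them were cluster 21 of classical monocyte-like cells and clusters 2, 8 and 26 of B cell-like cells. Leading genes were ranked by fold over the equally weighted mean of the other clusters, which was chosen after the pooled remainder had been seen to give unclear names. Clusters 13, 27 and 31, of cytotoxic or CXCR6 T cells with mixed CD4, CD8 and NK markers, were left unnamed; they held 1.57% ± 1.10 (SD, n = 4) of healthy, 8.86% ± 14.7 (n = 7) of MGUS and 5.24% ± 6.22 (n = 7) of WM cells. Naming each cell by its highest marker score gave the same class for 74.8% to 98.3% of cells, depending on class. The upper bound on free RNA, from marker genes of other cell types and barcodes under 100 UMIs, averaged 0.53% to 2.65% of UMIs by class and group.

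Shares used all cells of a library that remained after doublet removal as denominator, with 0.5 cells added to each class count before log2. Groups were compared with exact two-sided permutation tests of the difference in means, counting splits with at least as large an absolute difference, and Benjamini-Hochberg adjustment ran over the 39 comparisons of 13 classes and 3 contrasts. With 7 against 4 libraries the smallest possible p was 0.00303.

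For genes, raw UMI counts were summed per library over the cells of a class, where a library had at least 20 cells of it. This gave 17 libraries for classical monocyte-like cells (6 of WM), 18 for B cell-, CD4 T- and CD8 T-like cells and 15 for NK-like cells (5 of MGUS and 6 of WM). edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood F test, 1 mean per group and no other term) tested 7993, 9826, 10458, 7876 and 6188 genes in classical monocyte-, B cell-, CD4 T-, CD8 T- and NK-like cells, with a biological coefficient of variation of 0.375, 0.399, 0.324, 0.326 and 0.288. Calls had an adjusted p under 0.05 (Benjamini-Hochberg within class and contrast). The SE of a log2 fold change is its absolute value, before shrinkage, divided by the square root of F. DESeq2 1.42.0 was the other tool. CPM values are counts scaled by TMM library sizes.

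Named genes followed a rule fixed in advance. For each class and contrast these were the 10 highest and 10 lowest log2 fold changes among called genes with an average log2 CPM of at least 4, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, list members and the 5 genes of smallest p could be named. Antibody and receptor segments, HLA genes outside the MHC class II list and clone-based names were not named.

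The 28 gene lists covered type I interferon, interferon gamma, TNF and NF-kB inflammation, immediate early, heat shock, MHC class II, monocyte alarmin and granule, extrafollicular or atypical B cell, naive and follicular B cell, memory B cell, plasma cell and secretory, B cell receptor signalling, BCL2 family, proliferation, naive and stem-like T cell, cytotoxic, exhaustion, regulatory T cell, T helper 17, ribosomal protein and mitochondrially encoded genes. The others held markers of other cell types (granulocyte precursor, erythroid, platelet, immunoglobulin constant, monocyte, T cell and B cell genes). Each was tested in the classes fixed for it, 231 tests in all, with camera of limma 3.58.1 (preset inter-gene correlation 0.01, repeated with an estimated one) and with fry, which asks whether a list's genes move 1 way on balance. Adjusted p ran over the 231 tests. Of the list calls with the preset correlation, 0 held with an estimated one, and fry passed the naive and follicular (adjusted p = 0.0196) and BCL2 family (adjusted p = 0.0144) lists in B cell-like cells of WM against healthy.

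For the share of atypical B cell markers, each cell was thinned to 1000 UMIs by calculation, and cells with fewer were left out (10 healthy, 32 MGUS and 172 WM). The light chain ratio had 1 UMI added to each side and was used without its sign. Antibody counts had 1 added, were log2 transformed and centred on the cell's mean over tags, then averaged per library and class, and compared by exact permutation tests adjusted over 255 tests per contrast. Correlations over libraries used 100000 permutations.

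The gene tests were tested on simulated data with the fitted dispersions. In B cell-like cells with WM against healthy, 19 of 97 genes changed 2-fold and 88 of 99 changed 4-fold were recovered, with 4 of 9368 unchanged genes called. In monocyte-like cells with MGUS against healthy these were 21 of 95, 85 of 91 and 8 of 7572. Of 20 unchanged lists, 0 had a camera p under 0.05 in each class. The genes were simulated independently of each other, so this cannot show how camera behaves on lists whose genes move together. Over all classes, 2-fold changes were recovered for 16.8% to 49.5% of genes in the contrasts with healthy and 34.4% to 61.3% in WM against MGUS.

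The alternatives tried were DESeq2, upper-quartile normalization, other gene filters, other cell filters (1500 UMIs, 8% mitochondrial), no doublet removal, at least 50 cells, class by marker score, only the groups compared, a depth covariate, the replicate number as block, free RNA genes left out, other denominators, the percent scale and each library left out in turn. Added after the data were seen were the denominator without B and plasma cell-like cells, the unnamed T cell clusters counted as CD8 T-like, haemoglobin-rich barcodes counted as erythroid-like, leaving out libraries that lost over 10% of barcodes to the mitochondrial filter, the list tests with each library left out, those of monocyte-like cells without the 2 MGUS libraries of highest inflammation level, and those of lymphocytes with the upper bound of free RNA subtracted. Other software was numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, data.table (version 1.17.8) and matplotlib 3.10.9. The exome and ELISPOT measurements named in the design text are not part of the deposited matrices and were not analysed.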

Results

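RNA and 53 surface antibody tags were counted together in single cells (CITE-seq) of bone marrow mononuclear cells from 18 donors, with 1 library per donor. Of these, 4 libraries were from healthy donors, 7 from donors with monoclonal gammopathy of undetermined significance (MGUS, a precursor condition in which a B lineage clone makes a monoclonal antibody) and 7 from donors with Waldenström macroglobulinemia (WM, a lymphoma of IgM-secreting B cells and plasma cells). The healthy material was obtained from a commercial source and the patient material was not, so source and disease group cannot be told apart. Gene UMIs per library ranged from 21440766 to 47247998, and 3439 to 8190 cells per library passed the cell filters, 94235 in all. Once doublets were left out, 3344 to 7653 cells per library remained. The median depth per library was 3007 to 5186 UMIs and 988 to 1471 genes per cell. Cells were named by cluster, each name carrying "-like" because it rests on marker RNA, and genes were compared between donors on counts summed per library. The labels point to 1 question, whether B cell states, T and NK cell function and myeloid inflammation already differ in MGUS, before WM.

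MGUS was compared with healthy marrow to ask which cell states differ at the precursor stage. Classical monocyte-like cells made up 6.98% ± 4.28 (SD, n = 7) of cells in MGUS and 24.5% ± 7.40 (n = 4) in healthy marrow. In these monocyte-like cells, genes of the TNF and NF-kB inflammation list, which respond to inflammatory cytokines, stood higher in MGUS for 44 of 46 members, with a median log2 fold change of 1.55. Without the 2 MGUS libraries of highest inflammation level the median was 0.774. Heat shock and chaperone genes, which refold proteins under stress, stood higher for 16 of 17 members, with a median of 1.5. B cell-like cells of MGUS had higher levels of memory B cell genes (15 of 15 members, median 0.86) and lower levels of naive and follicular B cell genes (14 of 19 members, median -0.39). These 4 lists passed with a preset correlation between genes and none did with an estimated one (adjusted p of 0.400, 0.400, 0.400 and 0.327). No single gene passed in either class with edgeR, while DESeq2 called 139 in monocyte-like and 34 in B cell-like cells. The B cell-like class lay in different clusters in the 2 groups, so these lists may reflect the mix.

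The monocyte-like share differed by a log2 of -2.02, or 4.04-fold, with an exact p of 0.00606 and an adjusted p of 0.118 over 39 comparisons of shares. All 7 MGUS libraries lay below every healthy library, a separation with a chance share of 0.00606 if either direction counts, not adjusted over the 39 comparisons. On the scale of mean percent the difference was -17.5, with an adjusted p of 0.0295, so the call depends on the scale. Different clusters held the class. The SERPINB2, CCL2 and IL1B cluster (cluster 21) held 0.243% of healthy and 30.9% ± 39.7 of MGUS monocyte-like cells, and was over 50% of the class in 2 of 7 MGUS libraries. Conventional dendritic cell-like cells made up 1.03% in MGUS and 1.80% in healthy marrow (log2 difference -0.89, exact p = 0.0303, adjusted p = 0.174). Plasma cell-like cells made up 1.45% in MGUS and 0.723% in healthy marrow, and 0 of the 39 comparisons of shares passed over the 3 contrasts (11 with an unadjusted exact p under 0.05).

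No single gene passed in monocyte-like cells of MGUS with edgeR (7993 genes tested, 893 with an unadjusted p under 0.05, smallest adjusted p 0.0962), while DESeq2 called 139. The early response transcription factor EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315, GRCh38) averaged 151 ± 104 CPM (SD, n = 7) in MGUS and 14.5 ± 8.33 (n = 4) in healthy monocyte-like cells, a log2 fold change of 3.34 (SE 0.675, adjusted p = 0.0962). PTGS2, which makes prostaglandins (ENSG00000073756, chromosome 1, 186671791 to 186680427), averaged 251 ± 256 CPM against 30.5 ± 9.87 (log2 3.05, SE 0.675, adjusted p = 0.148). IL1B, an inflammatory cytokine (ENSG00000125538, chromosome 2, 112829751 to 112836903), averaged 3837 ± 4956 CPM against 249 ± 86.8 (log2 3.95, SE 1.20, adjusted p = 0.233). The chemokine CXCL8 averaged 5295 CPM against 807, the cytokine IL6 198 against 0.613 and the chaperone HSPA1A 1460 against 155, with adjusted p of 0.233, 0.179 and 0.232. Of the 46 TNF and NF-kB inflammation members, 30 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.93e-16, adjusted p = 0.400 with an estimated correlation). Of the 17 heat shock members, 15 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.77e-11, adjusted p = 0.400 with an estimated correlation). Immediate early genes, switched on within minutes of a stimulus, were higher for 24 of 28 members, 4 of them passing when adjusted over the list alone (median 0.46, or 0.26 without 1 of the healthy libraries, adjusted p = 3.1e-05, adjusted p = 0.470 with an estimated correlation). Proliferation genes were higher for 14 of 15 members (median 0.87, adjusted p = 0.0133, adjusted p = 0.679 with an estimated correlation). They did not pass in 4 of 11 settings with 1 library left out. The lowest median was 0.42, without 1 of the MGUS libraries (camera adjusted p = 0.258).

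Markers of other cells and of RNA state in the same monocyte-like cells did not pass: mitochondrially encoded genes were higher for 11 of 12 members (adjusted p = 0.0828), and the lists of erythroid, platelet and granulocyte precursor genes had no call. The list of monocyte alarmins and granule genes, among them the S100A8 and S100A9 danger signals, was higher for 11 of 21 members and did not pass (median 0.06, mean 0.18, test direction lower, adjusted p = 0.621). The interferon gamma list, tested in all 5 classes and 3 contrasts, passed in 0 of 15 tests.

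In B cell-like cells of MGUS 0 of 9826 genes passed with edgeR (645 with an unadjusted p under 0.05, 34 called by DESeq2). Cluster 6 held 95.8% ± 1.84 (SD, n = 4) of these cells in healthy marrow and 51.8% ± 23.1 (n = 7) in MGUS, and cluster 8 held 1.44% ± 0.676 and 26.3% ± 15.7. The mix was not separated from a change within cells for the lists below. Memory B cell genes had 2 of 15 members past the threshold when adjusted over the list alone (camera adjusted p = 1.94e-05, adjusted p = 0.400 with an estimated correlation), the repressor ZBTB32 (log2 1.70, adjusted p = 0.445) and the adhesion receptor ITGB1 (log2 1.25, adjusted p = 0.461). The naive and follicular list had an adjusted p of 0.00222 (adjusted p = 0.327 with an estimated correlation). Plasma cell and secretory genes were higher for 20 of 22 members (median 0.49, adjusted p = 0.00212, adjusted p = 0.499 with an estimated correlation). MHC class II genes, which present antigen to CD4 T cells, were lower for 10 of 12 members (median -0.26, or -0.15 without 1 of the MGUS libraries, adjusted p = 0.00191, adjusted p = 0.543 with an estimated correlation). BCL2 family genes, which set the threshold of cell death, were higher for 9 of 11 members (median 0.29, adjusted p = 0.00291, adjusted p = 0.316 with an estimated correlation). Their median was 0.15 without 1 of the MGUS libraries. The type I interferon list was higher for 29 of 31 members (median 0.79, adjusted p = 2.84e-04, adjusted p = 0.703 with an estimated correlation). This rested on 1 MGUS library, without which the list did not pass (median 0.19, adjusted p = 0.302). The stress lists were higher here too: heat shock for 15 of 17 members (median 0.66, adjusted p = 2.34e-08, adjusted p = 0.470 with an estimated correlation) and TNF and NF-kB inflammation for 26 of 28 (median 0.60, adjusted p = 1.36e-07, adjusted p = 0.463 with an estimated correlation). The extrafollicular or atypical B cell list was higher for 16 of 22 members and did not pass (median 0.34, adjusted p = 0.133). NEK6, a mitotic kinase, had the smallest p among B cell genes (log2 1.48, adjusted p = 0.118), and BBC3, which promotes cell death, had a log2 fold change of 2.09 (adjusted p = 0.298).

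T and NK cell-like cells of MGUS had 0 genes past the threshold with edgeR in each class (unadjusted p under 0.05 for 539 genes in CD4 T-like, 538 in CD8 T-like and 256 in NK-like cells, and 3, 24 and 1 called by DESeq2). Th17 genes, of helper cells that make IL-17, were higher for 7 of 8 members in CD4 T-like cells (median 0.58, adjusted p = 6.10e-04, adjusted p = 0.400 with an estimated correlation). Cluster 3 held 31.4% ± 20.9 (SD, n = 7) of CD4 T-like cells in MGUS and 15.25% ± 6.93 (n = 4) in healthy marrow, and cluster 5 held 18% ± 24.6 and 33.1% ± 19.3. This mix was not separated from a change within cells for the Th17 list or the cytotoxic list that follows. Cytotoxic genes were higher for 13 of 15 members in CD4 T-like cells (median 0.39, adjusted p = 0.00435, adjusted p = 0.470 with an estimated correlation) and lower for 19 of 24 in NK-like cells (median -0.20, adjusted p = 0.00609, adjusted p = 0.513 with an estimated correlation). Ribosomal protein genes were higher in the same NK-like cells for 28 of 28 members (median 0.23, adjusted p = 1.26e-05, adjusted p = 0.661 with an estimated correlation). FGFBP2, secreted by cytotoxic lymphocytes, had a log2 fold change of -0.66 in NK-like cells (adjusted p = 0.983). Exhaustion and checkpoint genes, among them inhibitory receptors and their regulators, were higher for 13 of 14 members in CD8 T-like cells (median 0.44, adjusted p = 0.00997, adjusted p = 0.400 with an estimated correlation). Their member BATF had a log2 fold change of 1.09 (adjusted p = 0.594). Cluster 7 held 64% ± 24.8 (SD, n = 7) of these cells in MGUS and 32.8% ± 14.8 (n = 4) in healthy marrow. GZMK and EOMES, both in the exhaustion list, are among the leading genes of that cluster. For this list too the mix was not separated from a change within cells. Heat shock genes were higher for 16 of 17 members in CD8 T-like cells (median 0.69, adjusted p = 1.71e-05, adjusted p = 0.53 with an estimated correlation). Their median was 0.36 without 1 of the MGUS libraries. With the preset correlation only, the heat shock list also passed in CD4 T-like cells (median 0.31). So did the inflammation list (0.24 in CD4 T-like, 0.27 in CD8 T-like cells) and the immediate early list (0.29 and 0.35). Of these further calls, only the immediate early list of CD8 T-like cells passed with each library left out in turn. Immunoglobulin constant and joining chain genes, of another cell type, were higher in CD8 T-like cells for 2 of 3 members (median 4.09, adjusted p = 0.0468, adjusted p = 0.470 with an estimated correlation). They did not pass in 5 of 11 settings with 1 library left out, such as without 1 of the healthy libraries (camera adjusted p = 0.434). IGHM, an antibody gene that T cells should lack, had a log2 fold change of 3.83 in CD4 T-like cells (adjusted p = 0.113).

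WM was compared with healthy marrow to ask what differs once lymphoma is established. B cell-like cells made up 38% ± 25.4 (SD, n = 7) of cells in WM and 13.4% ± 8.09 (n = 4) in healthy marrow, and 413 of 9826 genes changed in them, 225 rising and 188 falling. PDE4D, a cyclic AMP phosphodiesterase, fell 3.94 log2 units, and GPRIN3 rose 5.68. The survival gene BCL2 rose 1.23 log2 units and IL2RA, the alpha chain of the IL-2 receptor, rose 3.23. FCER2 (CD23), a marker of naive and follicular B cells, fell 1.85 log2 units. Plasma cell and secretory genes were higher for 22 of 22 members (median 0.80) and MHC class II genes lower for 12 of 12 (median -0.62). Both lists passed with the preset correlation only (adjusted p = 0.400 each with an estimated correlation). The class lay in different clusters in the 2 groups. Within cluster 6, which held most healthy B cell-like cells, the medians were 0.148 and -0.225 for the list genes tested there.

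GPRIN3 (ENSG00000185477, chromosome 4, 89236386 to 89308010) averaged 35.5 ± 17.4 CPM (SD, n = 7) in WM and 0.903 ± 1.52 (n = 4) in healthy B cell-like cells (SE of the log2 fold change 0.847, adjusted p = 7.87e-04). PDE4D (ENSG00000113448, chromosome 5, 58969038 to 60522120) averaged 4.11 ± 2.06 CPM against 60.9 ± 20.6 (SE 0.472, adjusted p = 1.06e-04). IL2RA (ENSG00000134460, chromosome 10, 6010689 to 6062370) averaged 99.3 ± 56.2 CPM against 10.4 ± 3.49 (SE 0.753, adjusted p = 0.0206). BCL2 (ENSG00000171791, chromosome 18, 63123346 to 63320128) averaged 210 ± 95.0 CPM against 89.2 ± 12.8 (SE 0.299, adjusted p = 0.0210). FCER2 (ENSG00000104921, chromosome 19, 7688758 to 7702146) averaged 47.7 ± 26.7 CPM against 172 ± 44.6 (SE 0.487, adjusted p = 0.0381). Among the largest rises were ATP1B1, a sodium pump subunit (3.67), the transcription factors BHLHE41 (3.65) and BATF (3.54), the pseudokinase TRIB1 (3.46), ZNF804A (3.16) and PPFIBP2 (3.09). The largest falls also took in CLEC2B (-3.15), COL19A1 (-2.91), BCL7A (-2.72), the phospholipid phosphatase PLPP5 (-2.53), the ligand-activated transcription factor AHR (-2.53) and the protease ADAM28 (-2.15). For each gene named here, all 7 WM libraries lay beyond the healthy median.

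By list, 9 of the 22 plasma cell and secretory genes rose when adjusted over the list alone and 3 over all genes (camera adjusted p = 6.36e-05, adjusted p = 0.400 with an estimated correlation). They were led by ITM2C (log2 2.97), DERL3 (1.67), which clears misfolded secretory proteins, and the transcription factor CREB3L2 (2.21). Memory B cell genes were higher for 13 of 15 members, 5 rising both when adjusted over the list alone and over all genes (median 0.94, adjusted p = 4.98e-04, adjusted p = 0.402 with an estimated correlation). These included ITGB1 (2.57, adjusted p = 0.00125), the repressor ZBTB32 (2.03) and the BAFF and APRIL receptor TNFRSF13B (1.81). Naive and follicular genes were lower for 11 of 19 members, with 6 falling when adjusted over the list alone and 4 over all genes (median -0.88, adjusted p = 2.44e-04, adjusted p = 0.327 with an estimated correlation). BTLA, an inhibitory receptor (-1.65), and BACH2, a repressor of plasma cell differentiation (-0.88), were among the falls. MHC class II genes had 5 of 12 falling when adjusted over the list alone and 1 over all genes (adjusted p = 2.33e-05, adjusted p = 0.400 with an estimated correlation). That 1 gene was HLA-DMA, which loads peptides (-1.11, SE 0.255, adjusted p = 0.0145), and HLA-DRA had a log2 fold change of -0.75 (adjusted p = 0.0507). BCL2 family genes were higher for 9 of 11 members, 3 rising under both adjustments (median 0.48, adjusted p = 0.0113, adjusted p = 0.327 with an estimated correlation). Beside BCL2, these were BBC3 (2.39) and PMAIP1 (1.95), both of which promote cell death.

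TNF and NF-kB inflammation genes were higher for 23 of 28 members in these B cell-like cells, with 4 rising and 1 falling when adjusted over the list alone and 2 over all genes (median 0.67, adjusted p = 0.0136, adjusted p = 0.768 with an estimated correlation). The 2 were the NF-kB cofactor NFKBIZ (2.15) and the cytokine IL6 (1.88, 97.3 CPM against 25.9). Ribosomal protein genes were lower for 27 of 28 members (median -0.27, adjusted p = 0.00167, adjusted p = 0.833 with an estimated correlation). The extrafollicular or atypical list did not pass (13 of 22 higher, median 0.26, mean -0.02, test direction lower, adjusted p = 0.598), with 3 members rising and 2 falling when adjusted over the list alone. Of these, the IL-10 receptor chain IL10RA (1.29, with 6 of 7 WM libraries above the healthy median) rose over all genes as well, and TFEC (-2.87), a transcription factor of myeloid cells, fell. B cell receptor signalling genes were higher for 14 of 24 members and did not pass (median 0.09, adjusted p = 0.860), although the adaptor BLNK rose 1.66. T cell genes were lower for 5 of 5 members (adjusted p = 0.258). Antibody V, D and J segments made up 35 of the 413 calls, all lower, and another 172 calls were of genes under an average log2 CPM of 4.

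**Figure D1:**
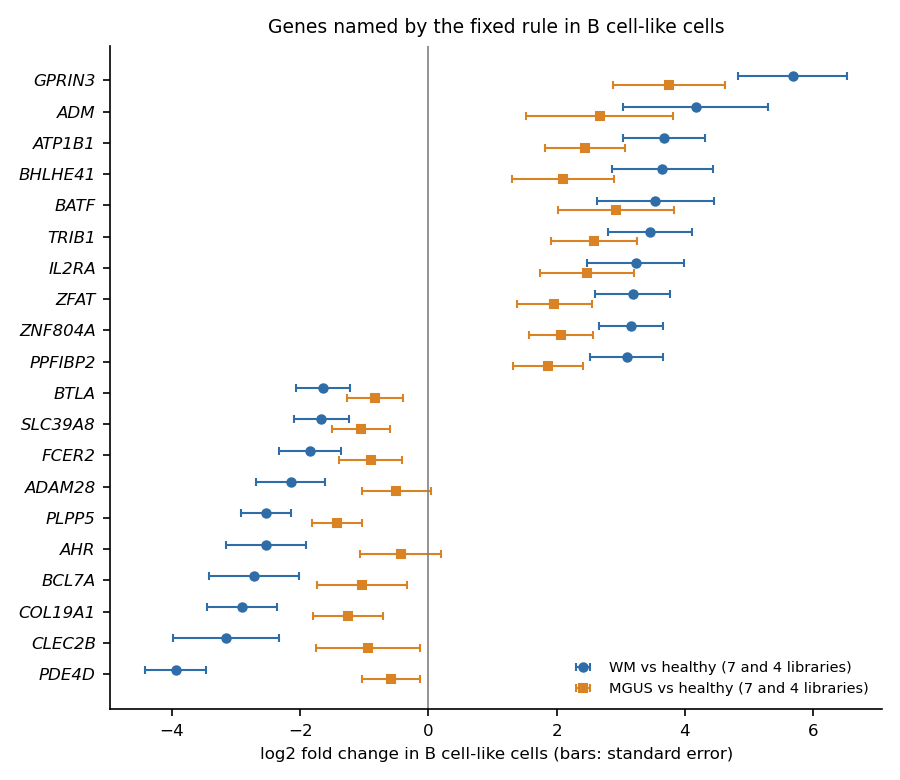
Log2 fold change (x axis, points, with bars of 1 SE) of 20 genes in B cell-like cells for WM against healthy and MGUS against healthy. PDE4D stands at -3.94 and GPRIN3 at 5.68 in WM against healthy.

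The number of B cell calls depended on the libraries taken: without any 1 healthy library it was 184 to 246. In cluster 6, which held 95.8% of healthy, 51.8% of MGUS and 7.2% of WM B cell-like cells, 214 of 218 called genes kept their sign, with a median signed log2 fold change of 0.93 against 1.32 in the whole class. The same healthy libraries enter both values, which alone favours the same sign. Within that cluster the median of the plasma cell list was 0.15 and that of the naive list -0.12, while the memory list stood at 1.14. The MHC class II list stood at -0.23 there, against -0.62 in the whole class, so part of its difference may come from the mix of clusters. The largest cluster of each WM library held on average 83.3% of its B cell-like cells, but it was not the same cluster in each. Cluster 8 was over 50% of the class in 2 WM libraries and clusters 2, 14, 19 and 26 in 1 each. A single library gave 97.0% of the cells of cluster 2, and 1 library each gave 87.4% of cluster 14 and 88.6% of cluster 19.

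Other classes in WM against healthy had fewer calls. In CD8 T-like cells 24 of 7876 genes changed, 17 rising and 7 falling, but the calls depended on the setting. There were 0 with a depth covariate, with the replicate number as block, without the libraries that lost over 10% of barcodes to the mitochondrial filter, or with the unnamed T cell clusters counted. There was 1 with only the 2 groups compared, 8 with classes by marker score, 12 from 1500 UMIs per cell and 114 with DESeq2. The class lay in different clusters: cluster 7 held 32.8% ± 14.8 (SD, n = 4) of it in healthy and 71.7% ± 30.9 (n = 7) in WM, and cluster 23 held 34.4% ± 19.4 and 12.2% ± 10.6. The mix was not separated from a change within cells. FYN, a kinase of T cell receptor signalling (ENSG00000010810, chromosome 6, 111660332 to 111873452), rose to 289 ± 81.2 CPM from 127 ± 33.8 (SD, log2 1.20, SE 0.247, adjusted p = 0.0462). HMGB2, a chromatin protein (ENSG00000164104, chromosome 4, 173331695 to 173335125), fell to 186 ± 59.8 CPM from 521 ± 35.9 (log2 -1.48, SE 0.320, adjusted p = 0.0473). The kinase CSNK1D (1.19), REEP5 (1.34) and AGO2 (1.60), which works in RNA silencing, rose, and the cell cycle inhibitor CDKN2D (-1.23) and COQ8A (-1.18) fell. In NK-like cells 15 of 6188 genes changed, 8 rising and 7 falling. There were 0 with classes by marker score or the replicate number as block, 4 from 50 cells per library and 7 with a depth covariate. There were 24 with only the 2 groups compared, 81 with DESeq2 and 154 without the expression filter. REEP5, which shapes the endoplasmic reticulum (ENSG00000129625, chromosome 5, 112876379 to 112922539), rose to 235 ± 51.9 CPM from 98.3 ± 7.83 (log2 1.27, SE 0.213, adjusted p = 0.0219). PPP1R14B (3.40), the translation repressor EIF4EBP1 (2.19) and AGO2 (1.46) also rose, and GCH1 (-1.19), the cochaperone DNAJB6 (-0.90) and the histone gene H3F3B (-0.86) fell. In CD4 T-like cells 7 of 10458 genes changed, 3 rising and 4 falling (1 to 4 in the settings that weakened it, 99 with DESeq2). BIRC2, an inhibitor of apoptosis, rose to 89.2 ± 22.8 CPM from 42.7 ± 5.11 (log2 1.06, SE 0.183, adjusted p = 0.0259) and COQ8A fell (-1.45). IGHM, from B lineage cells, rose as well in CD4 T-like cells (3.91, 10.7 CPM against 0.728). In MGUS against healthy, which uses the same healthy libraries, FYN stood at 1.07 and COQ8A of CD8 T-like cells at -1.09 (both adjusted p = 0.288).

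Cytotoxic genes were lower for 20 of 24 members in NK-like cells of WM, 2 of them when adjusted over the list alone and 0 over all genes (median -0.33, adjusted p = 0.00184, adjusted p = 0.470 with an estimated correlation). Type I interferon genes were lower for 24 of 31 members in NK-like cells (median -0.46, adjusted p = 1.37e-06, adjusted p = 0.53 with an estimated correlation), and so were TNF and NF-kB inflammation genes for 20 of 26 (median -0.36, adjusted p = 1.74e-04, adjusted p = 0.400 with an estimated correlation). Regulatory T cell genes were higher for 13 of 14 members in CD4 T-like cells (median 0.66, adjusted p = 0.00764, adjusted p = 0.510 with an estimated correlation). Their median was 0.39 without 1 of the WM libraries. Th17 genes were higher for 7 of 8 (median 0.52, adjusted p = 0.0437, adjusted p = 0.615 with an estimated correlation). Cluster 17 held 23.2% ± 38.8 (SD, n = 7) of CD4 T-like cells in WM, 2.01% ± 2.07 (n = 7) in MGUS and 3.15% ± 1.35 (n = 4) in healthy marrow. The WM mean came from 2 libraries, in which the cluster was over 50% of the class, and the median share of all cells was 0.196% in WM and 0.671% in healthy marrow. Exhaustion genes were higher for 12 of 13 members in CD4 T-like cells and did not pass (median 0.61, adjusted p = 0.0640). Naive and stem-like T cell genes were lower for 12 of 17 members in CD8 T-like cells (adjusted p = 0.0832). Ribosomal protein genes were lower for 28 of 28 members in CD8 T-like cells (median -0.34, adjusted p = 4.15e-08, adjusted p = 0.615 with an estimated correlation), and monocyte genes, of another cell type, for 6 of 6 in CD4 T-like cells (median -0.78, or -0.52 without 1 of the WM libraries, adjusted p = 0.00787, adjusted p = 0.400 with an estimated correlation).

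Classical monocyte-like cells made up 5.46% ± 3.67 (SD, n = 7) of cells in WM, a log2 difference from healthy of -2.83 (exact p = 0.0273, adjusted p = 0.174), with no overlap between the groups, a separation with a chance share of 0.00606. The share of cells of the classical monocyte-like class, WM vs healthy, differed by -2.1 without B cell-like and plasma cell-like cells in the denominator, and by -19.0 on the mean percent scale (adjusted p = 0.0295). NK-like cells made up 2.02% ± 2.05 in WM and 7.18% ± 4.79 in healthy marrow (log2 -2.20, exact p = 0.0242, adjusted p = 0.174). Granulocyte-monocyte precursor-like cells made up 0.860% and 3.08% (log2 -3.07, exact p = 0.0394, adjusted p = 0.174), and conventional dendritic cell-like cells 0.529% and 1.80% (log2 -2.58, exact p = 0.0424, adjusted p = 0.174). The B cell-like share differed by a log2 of 1.39 (exact p = 0.0455, adjusted p = 0.174). In monocyte-like cells 0 of 7993 genes passed with edgeR (779 with an unadjusted p under 0.05, 46 by DESeq2, smallest adjusted p 0.0599), and FAM20A had a log2 fold change of 3.20 (adjusted p = 0.0599). The TNF and NF-kB inflammation list was higher for 37 of 46 members and did not pass (median 0.23, adjusted p = 0.134). B cell genes, of another cell type, were higher in the monocyte-like cells for 2 of 2 members (median 1.96, or 1.02 without 1 of the healthy libraries, adjusted p = 0.00112, adjusted p = 0.327 with an estimated correlation), CD79A at 2.66 among them. The T and NK cell counts needed all 4 healthy libraries: without any 1 of them the CD8 T-like and NK-like counts were 0, and the CD4 T-like count was 0 to 2. The fold changes moved less, with FYN at 1.07 to 1.39 in CD8 T-like and REEP5 at 1.19 to 1.37 in NK-like cells over all libraries left out in turn.

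**Figure D2:**
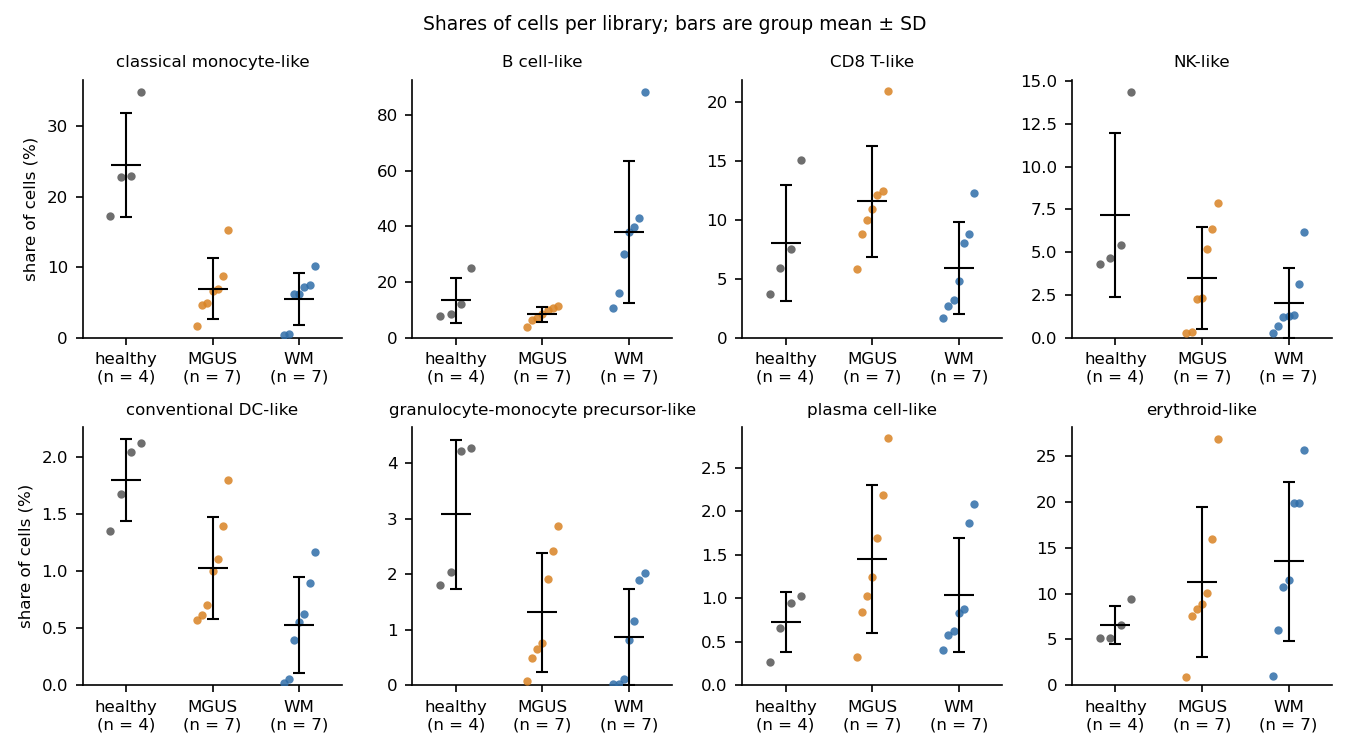
Percent of the cells of each library (y axis, 1 point per library, with mean and SD per group) for 8 classes in healthy, MGUS and WM marrow. B cell-like cells averaged 38% in WM and 8.39% in MGUS, and classical monocyte-like cells 24.5% in healthy marrow.

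WM was compared with MGUS to ask what separates the lymphoma from the precursor. B cell-like cells made up 38% ± 25.4 (SD, n = 7) of cells in WM and 8.39% ± 2.69 (n = 7) in MGUS, a 3.92-fold difference of geometric means. In these cells 32 genes changed, 1 rising and 31 falling, with PDE4D again falling (log2 -3.36). The count was 14 to 59 with each library left out, 2 among genes with an average log2 CPM of at least 4, 4 with only the 2 groups compared, 11 with classes by marker score and 105 with DESeq2. The inflammation and heat shock genes that were higher in MGUS monocyte-like cells were lower in WM: 45 of 46 and 17 of 17 members, with medians of -1.12 and -1.53. Both lists passed with the preset correlation only (adjusted p = 0.400 and 0.327 with an estimated correlation). The monocyte-like class lay in different clusters. Cluster 9 held 15.27% ± 21.1 (SD, n = 7) of it in MGUS and 52.45% ± 24.9 (n = 7) in WM. The IL1B cluster (cluster 21) held 30.9% ± 39.7 and 9.51% ± 20.3. This mix was not separated from a change within cells. No single gene passed in monocyte-like cells with edgeR, while DESeq2 called 41, and the same MGUS libraries enter both contrasts. Type I interferon genes were lower in WM for 29 of 31 members in NK-like cells (median -0.96), and 29 of 35 in CD8 T-like cells (median -0.47), and the size of both differences depended on 1 MGUS library. In both classes the list passed with the preset correlation only.

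The B cell-like share differed by a log2 of 1.97 (exact p = 0.00175, adjusted p = 0.0682), with all 7 WM libraries above the MGUS median, and passed on the mean percent scale (29.6, adjusted p = 0.0295). CD8 T-like cells made up 5.93% ± 3.87 in WM and 11.6% ± 4.68 in MGUS (log2 -1.17, exact p = 0.0227, adjusted p = 0.174), and -0.39 with B and plasma cell-like cells left out of the denominator. Plasmacytoid dendritic cell-like cells differed by -1.27 (exact p = 0.0466, adjusted p = 0.174) and conventional ones by -1.68 (exact p = 0.0490, adjusted p = 0.174). Both are shares of all cells, with the B cell-like ones that were more numerous in WM included. With class by highest marker score the plasmacytoid difference was 1.05 (exact test, adjusted p = 0.277), of the other sign. PDE4D averaged 4.11 ± 2.06 CPM (SD, n = 7) in WM and 41.3 ± 21.7 (n = 7) in MGUS (SE 0.442, adjusted p = 5.83e-04). FTH1, which stores iron (ENSG00000167996, chromosome 11, 61959718 to 61967660), fell to 3274 ± 841 CPM from 5917 ± 936 (log2 -0.85, SE 0.158, adjusted p = 0.0167). CYB5R3, a reductase (ENSG00000100243, chromosome 22, 42617840 to 42649568), rose to 96.6 ± 12.4 CPM from 55.6 ± 15 (log2 0.80, SE 0.167, adjusted p = 0.0389). ITGB1 stood at 1.32 (adjusted p = 0.0899) and BLNK at 1.17 (adjusted p = 0.0640). Antibody V, D and J segments made up 9 of the 31 falls, and another 20 calls were of genes under an average log2 CPM of 4. In the remaining classes SLC1A4, an amino acid transporter, rose in CD8 T-like cells to 19 ± 8.04 CPM from 6.18 ± 1.61 (log2 1.63, SE 0.283, adjusted p = 0.0492), and edgeR called 0 genes in monocyte-like, CD4 T-like and NK-like cells (655, 353 and 283 with an unadjusted p under 0.05, and 41, 1 and 0 by DESeq2).

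In monocyte-like cells the heat shock list had an adjusted p of 4.89e-19 (15 of 17 past the threshold when adjusted over the list alone, 0 over all genes; adjusted p = 0.327 with an estimated correlation). The TNF and NF-kB inflammation list had an adjusted p of 6.12e-18 (25 of 46 when adjusted over the list alone, 0 over all genes; adjusted p = 0.400 with an estimated correlation). PTGS2 stood at -2.75, the cytokine IL1A at -4.61 and the chaperone DNAJB1 at -2.36 (each adjusted p = 0.322). Mitochondrially encoded genes were lower in WM for 12 of 12 members (median -0.24, adjusted p = 0.00653, adjusted p = 0.699 with an estimated correlation), and immunoglobulin constant genes of B lineage cells were higher for 4 of 4 (median 2.62, adjusted p = 0.00997, adjusted p = 0.491 with an estimated correlation). The latter did not pass in 4 of 13 settings with 1 library left out. Their lowest median was 0.58, without 1 of the WM libraries (camera adjusted p = 0.175). In CD8 T-like cells heat shock genes were lower for 17 of 17 members (median -0.63, adjusted p = 5.22e-13, adjusted p = 0.400 with an estimated correlation) and TNF and NF-kB inflammation genes for 27 of 29 (median -0.37, adjusted p = 2.58e-09, adjusted p = 0.316 with an estimated correlation). In CD4 T-like cells TNF and NF-kB inflammation genes were lower for 26 of 28 members (median -0.35, adjusted p = 2.02e-08, adjusted p = 0.327 with an estimated correlation), and erythroid genes, of another cell type, were higher for 8 of 10 (median 0.47, adjusted p = 0.0244, adjusted p = 0.591 with an estimated correlation). In NK-like cells heat shock genes were lower for 16 of 16 members (median -0.81, adjusted p = 2.05e-08, adjusted p = 0.402 with an estimated correlation). They were lower for 13 of 16 without 1 of the MGUS libraries (median -0.22, adjusted p = 0.00820).

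The interferon lists had adjusted p of 1.06e-12 in NK-like cells (adjusted p = 0.400 with an estimated correlation), 1.37e-06 in CD8 T-like cells (adjusted p = 0.524 with an estimated correlation) and 2.33e-05 in B cell-like cells (adjusted p = 0.661 with an estimated correlation). Without 1 MGUS library their medians were -0.51, -0.24 and -0.06, and the list no longer passed in B cell-like cells (adjusted p = 0.624), where it was lower for 27 of 31 members with all libraries (median -0.62). The antiviral genes MX1 and ISG15 stood at -2.53 and -2.06 in NK-like cells (both adjusted p = 0.999). In B cell-like cells the plasma cell and secretory list was higher for 21 of 22 members (median 0.47, adjusted p = 0.00154, adjusted p = 0.476 with an estimated correlation) and MHC class II lower for 11 of 12 (median -0.35, adjusted p = 0.00154, adjusted p = 0.53 with an estimated correlation). Cluster 6 held 51.8% of the class in MGUS and 7.2% in WM, and this mix was not separated from a change within cells for the B cell lists here. The extrafollicular or atypical list was lower for 15 of 22 members, with 2 rising and 5 falling when adjusted over the list alone (median -0.20, adjusted p = 0.00961, adjusted p = 0.400 with an estimated correlation). Without 1 of the WM libraries it was higher for 10 and lower for 12, and did not pass (median -0.06, adjusted p = 0.0558). TFEC stood at -3.08 (adjusted p = 0.0651) and the chemokine receptor CXCR3 at -1.75 (adjusted p = 0.252). Ribosomal protein genes were lower for 28 of 28 members (median -0.22, adjusted p = 2.24e-06, adjusted p = 0.661 with an estimated correlation). Over all classes and contrasts, 78 of 231 list tests passed with a preset correlation and 0 with an estimated one, so the list calls rest on the preset value. With each library left out in turn, 51 of the 78 calls passed throughout and 27 did not pass without at least 1 library, and for 16 of the 78 the median fell under 50% of its value or changed sign. Among the 27 were the exhaustion list of CD8 T-like cells and the cytotoxic list of CD4 T-like cells in MGUS against healthy, and the Th17 list and the inflammation list of B cell-like cells in WM against healthy. In WM against MGUS they included the extrafollicular or atypical list, and in monocyte-like cells the mitochondrially encoded and immunoglobulin constant genes. The erythroid genes of CD4 T-like cells in WM against MGUS were among them too, lost in 7 of 14 settings (median 0.28, camera adjusted p = 0.188 without 1 WM library).

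**Figure D3:**
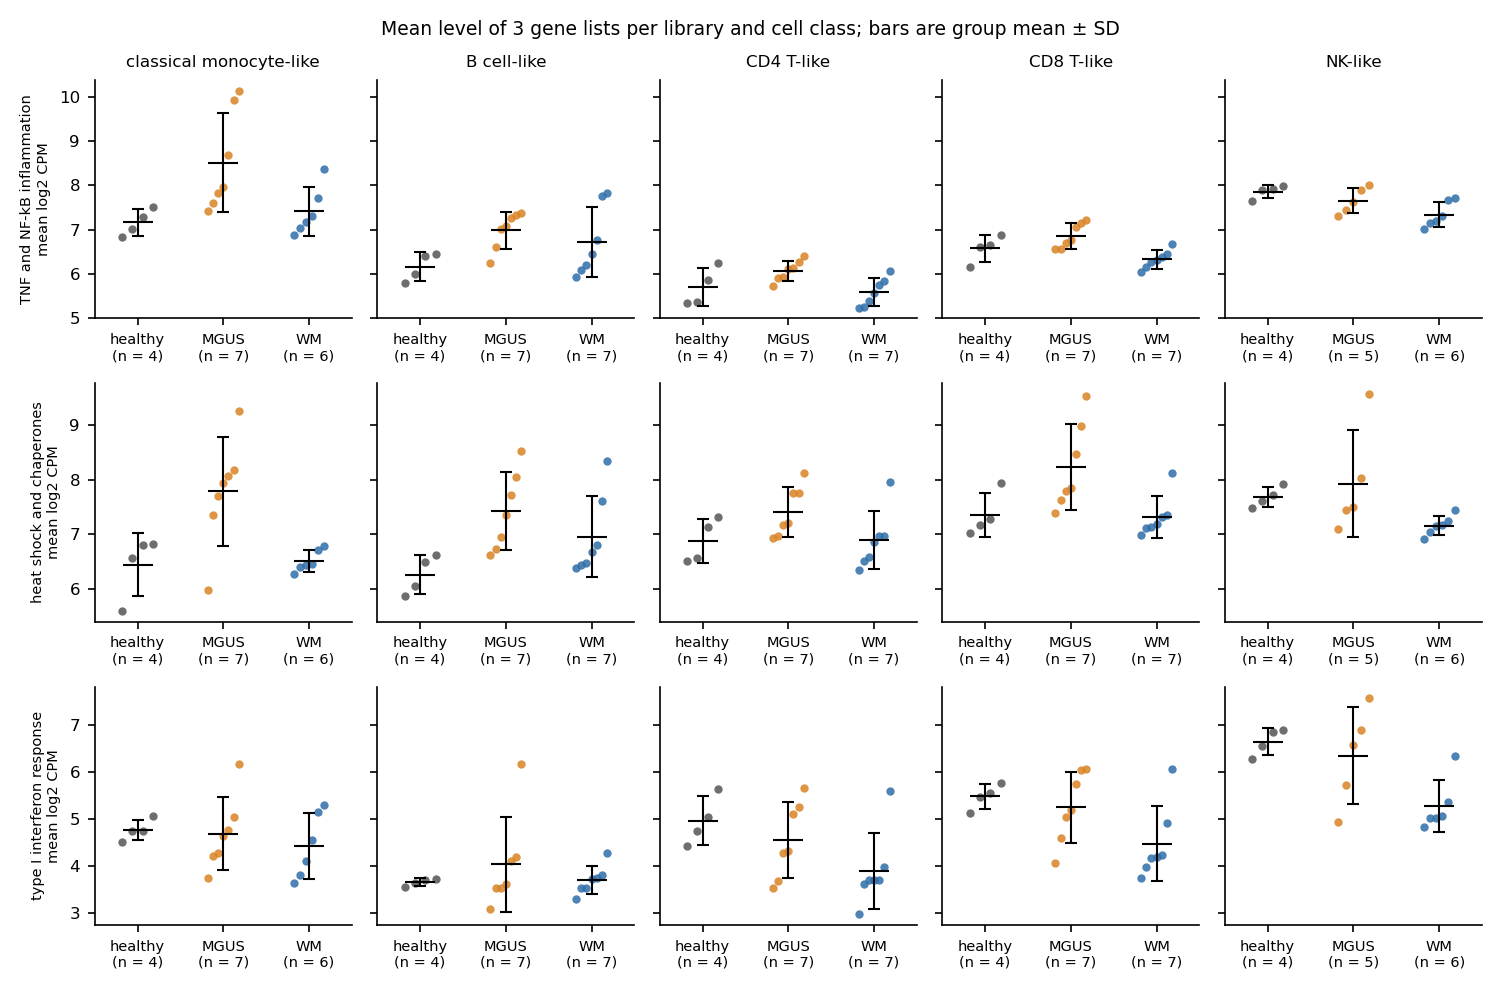
Mean log2 CPM of the TNF and NF-kB inflammation, heat shock and type I interferon lists (y axis, 1 point per library, with group means) in the tested classes. The inflammation list of classical monocyte-like cells differs between MGUS and healthy by a mean of 1.34.

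No gene passed in both MGUS against healthy and WM against healthy with edgeR, since MGUS against healthy had no calls. DESeq2 called 32 shared genes in B cell-like, 19 in CD8 T-like, 11 in monocyte-like, 3 in CD4 T-like cells and 1 in NK-like cells. Both contrasts use the same 4 healthy libraries, which alone makes their fold changes covary. In B cell-like cells the covariance of fold changes was 0.298, against a mean of 0.130 in 20 simulations without change and of 0.244 when each contrast used its own 2 healthy libraries. The correlation over genes, which are not independent replicates, was 0.748, against 0.610 in the simulations.

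Cells with a UMI of ITGAX, TBX21 or FCRL5, markers of atypical B cells, made up 1.44% ± 0.41 (SD, n = 4) of B cell-like cells in healthy, 2.39% ± 0.786 (n = 7) in MGUS and 1.5% ± 0.555 (n = 7) in WM at 1000 UMIs per cell. The exact p were 0.0636 for MGUS against healthy, 0.861 for WM against healthy and 0.0350 for WM against MGUS, with adjusted p of 0.0955, 0.861 and 0.0955. Taken singly, TBX21 passed in WM against MGUS (0.106% ± 0.0874 and 0.43% ± 0.308, n = 7 and 7, exact p = 0.0122, adjusted p = 0.0367 over 3 contrasts), while FCRL5 and ITGAX did not (exact tests, adjusted p = 0.204 and 0.448). Without thinning TBX21 did not pass either (exact p = 0.0431, adjusted p = 0.118). WM monocyte-like cells gave 0.0642% ± 0.0814 (n = 6) for it at 1000 UMIs, close to the share in WM B cell-like cells. CD4 T-like cells gave 0.527%, 0.656% and 0.919%, of which TBX21, also a gene of helper T cells, made up 0.496%, 0.622% and 0.873%, so these are no measure of background. Median depths before thinning were 3761, 3535 and 3954 UMIs in B cell-like and 4564, 4098 and 4730 in CD4 T-like cells. The absolute log2 ratio of the light chain constant genes in B cell-like cells, which grows with a dominant clone, averaged 0.641 ± 0.299 in healthy (n = 4), 0.615 ± 0.706 in MGUS (n = 7) and 2.44 ± 2.22 in WM (n = 7), with an exact p of 0.0338 for WM against MGUS (adjusted p = 0.101) and 0.124 for WM against healthy (adjusted p = 0.186).

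Surface proteins were compared as 51 tags in each of 5 classes, 255 tests per contrast, and 0 passed (exact tests, 49, 21 and 48 with an unadjusted p under 0.05 for MGUS against healthy, WM against healthy and WM against MGUS). With 7 against 4 libraries the smallest possible exact p was 0.00303. Over 255 tests a tag could pass against healthy only if many tags reached that floor together. The lack of calls therefore does not show that the surface proteins were alike. The tags with the smallest p in B cell-like cells of WM were picked after the values were seen. There the complement receptor CD21 stood at 1.07 ± 0.668 centred log2 units against 3.36 ± 0.484 in healthy (n = 7 and 4, exact p = 0.00303, adjusted p = 0.193), and surface IgD was 2.18 lower. In MGUS these tags were 1.65 and 2.21 lower than in healthy (exact p = 0.00606 and 0.0121, adjusted p = 0.103 and 0.134). CD25, the protein of IL2RA, was 1.57 higher in WM than in healthy B cell-like cells and 0.99 higher than in MGUS (exact p = 0.00303 and 0.00175, adjusted p = 0.193 and 0.258). In MGUS against healthy the granulocyte protein CD66b was 1.54 higher on monocyte-like, 1.65 on CD4 T-like and 1.63 on CD8 T-like cells, and CD185 (CXCR5), a follicle homing receptor, was 1.05 lower on B cell-like cells (each exact p = 0.00303, adjusted p = 0.0966). Of the antibody counts, 33.7% ± 12 (SD, n = 7) lay in cells in MGUS and 62.2% ± 14.8 (n = 4) in healthy libraries, so free antibody was not separated from binding in the CD66b values.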

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

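Chosen only after the result was seen were both tests of free RNA in lymphocytes, of whether the healthy libraries differ from both patient groups, of the cluster mix behind the plasma cell and naive lists, of a pair of MGUS libraries, and of a library state behind the inflammation and immediate early lists.

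In monocyte-like cells of MGUS the inflammation, heat shock and immediate early lists were higher than in healthy and in WM libraries. A single library is argued against, since the lowest median of the inflammation list with 1 MGUS library left out was 1.21, against 1.55 with all, and so is depth per cell, since the median with the depth covariate was 1.51. A pair of libraries carried about 50% of it: 2 MGUS libraries had inflammation levels of 9.929 and 10.13 mean log2 CPM, against 7.412 to 8.671 in the others, and without them the median was 0.774 (42 of 45 members higher, adjusted p = 6.8e-11 with the preset correlation). The IL1B cluster was over 50% of the class in 2 of 7 MGUS libraries. A state of the whole library fits for the heat shock list: after removing group means the heat shock level in monocyte-like and CD4 T-like cells correlated over libraries (Pearson r = 0.682, permutation p = 0.00751, Spearman rho = 0.615, permutation p = 0.0292, r = 0.485 without the 2 farthest libraries, adjusted p = 0.0401 over 16 relations). It also correlated with B cell-like cells (r = 0.714, permutation p = 0.00343, adjusted p = 0.0401), but not past the threshold with CD8 T-like and NK-like cells (r = 0.583 and 0.632, permutation tests, adjusted p = 0.217 and 0.346). The inflammation list correlated with CD4 T-like cells (r = 0.545, permutation p = 0.00682, adjusted p = 0.0401), but r was 0.0738 with CD8 T-like cells. For the immediate early list r was -0.122 to 0.111, so a library state cannot be told apart there. For the same lists in lymphocytes, 11 of 11 calls in WM against MGUS stayed without genes that could be free RNA. That test decides nothing, since only 2 of the 286 list genes were removed. A second test, added because the first was void, subtracted the upper bound of free RNA from each library's counts. It kept 11 of 11 calls, with medians at 0.961 to 1.09 times their values, so free RNA as measured in near-empty barcodes is argued against. Handling, time to processing and a biological response to MGUS thus stay open, and a biological one was not tested separately.

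The genes that changed in B cell-like cells of WM against healthy could reflect a different mix of B cell clusters. For the called genes as a whole, the median signed log2 fold change was 0.933 within cluster 6 and 1.32 in the whole class. Of 218 genes, 214 had the same sign. This met the bound set in advance against the mix as the whole cause. The genes were called with the same healthy libraries, in which cluster 6 held 95.8% of the class, and that alone favours the same sign. The test therefore cannot decide, and only 218 of the 413 calls could be looked up. Only 597 WM and 2850 healthy cells were in that cluster, and 16 of 5002 genes passed there. For the plasma cell and naive lists the mix cannot be told apart: their medians within the cluster were 0.148 and -0.124, against 0.742 and -0.512 for the same genes in the whole class. The MHC class II list, not tested separately, shrank there too, to -0.225 from -0.615. The disease itself stays open as a biological explanation, and so does the source of the healthy material, which goes with the group.

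The 46 calls in CD4 T-, CD8 T- and NK-like cells of WM against healthy, of 42 distinct genes, could come from a difference of the healthy libraries from both patient groups. Their median signed log2 fold change was 1.36 in WM against healthy, 0.898 in MGUS against healthy, where the same healthy libraries alone favour the same sign, and 0.47 in WM against MGUS. The value of 0.47 lies between the bounds set for either answer, so this cannot be told apart. Both disease and the source of the healthy material stay open.

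Other splits of the libraries into groups of the same sizes were counted, 100 per comparison with the real one included. In WM against healthy only the real split, 1 of 100, reached its count in B cell-like (413, highest other 152), CD8 T-like (24, highest other 2) and NK-like cells (15, highest other 2). Before any adjustment, this argues against chance in those classes. In CD4 T-like cells 2 of 100 splits gave as many genes (7, highest other 11). That met the bound set in advance for arguing against chance, but another split called more genes, so chance cannot be excluded there. In WM against MGUS 4 of 100 splits gave as many genes in B cell-like cells (32, highest other 329), and 6 of 100 did in CD8 T-like cells (1, highest other 183). The 4 of 100 met the bound set in advance for arguing against chance, but another split called far more genes. Chance cannot be excluded in either class. None of these shares of splits, those against healthy included, was adjusted for the number of comparisons. Where the real count was 0, all 100 of 100 splits gave as many. Their highest other counts were 212, 1 and 107 in monocyte-like cells (MGUS against healthy, WM against healthy and WM against MGUS), 2 in B cell-like and CD8 T-like and 1 in NK-like cells for MGUS against healthy, 81 and 496 in CD4 T-like cells (MGUS against healthy and WM against MGUS) and 40 in NK-like cells (WM against MGUS). Splits that call many more genes than the real one show differences among libraries that do not follow the groups.

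Values far from their group's others were looked for in 129 groups, with 1 in 20 expected to be picked by chance, and 12 groups held 1. A WM library had a log2 share of CD4 T-like cells of -4.849, and an MGUS library a log2 share of erythroid-like cells of -6.762. The mitochondrial filter removed 15.85% of barcodes in a WM library. In mean log2 CPM, the type I interferon list stood at 6.169 in B cell-like cells of an MGUS library, without which its calls there did not pass, at 5.594 in CD4 T-like cells and at 6.343 in NK-like cells of WM libraries. The heat shock list stood at 7.968 in CD4 T-like and 8.129 in CD8 T-like cells of WM libraries. The ribosomal protein list stood at 12.59 in CD4 T-like cells of a healthy library and 11.72 in CD8 T-like cells of a WM library. Immediate early genes stood at 7.82 in NK-like cells of an MGUS library and 8.474 in monocyte-like cells of a WM library.

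The inflammation list differed between MGUS and healthy by 0.9773 log2 more in monocyte-like than in CD4 T-like cells (1.34 and 0.366, exact p = 0.0485, adjusted p = 0.5 over 15 tests). Barcodes rich in haemoglobin RNA but with too few genes to count as cells, which the comparisons leave out, were more numerous in 1 MGUS library and 2 WM libraries than in any healthy library, where the most was 187.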

How the results depend on the processing

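The limits are the 4 healthy libraries from another source than the patient libraries, the wide spread among donors, and the list tests, of which 0 of 231 hold with an estimated inter-gene correlation against 78 with the preset one. Chosen after the data were seen were the settings without libraries that lost over 10% of barcodes to the mitochondrial filter (MGUS 1, MGUS 7 and WM 4), with the unnamed T cell clusters counted as CD8 T-like, with haemoglobin-rich barcodes counted as erythroid-like, without B and plasma cell-like cells in the denominator, the list tests with each library left out and those without the 2 MGUS libraries of highest inflammation level. The cause of each change was not tested. Counts of genes stayed within 1.5 times of the main count in 269 of 385 settings. This total includes main counts of 0 that stayed at 0, so it does not show how stable the counts above 0 were. The count fell by more in 72 settings, all of them with a main count above 0. Shares kept their direction and their side of the threshold in 784 of 819 settings. No share passed in the main setting, so keeping that side only means staying short of the threshold. The size of a share difference could move within that. Without B and plasma cell-like cells in the denominator, the CD8 T-like log2 difference in WM against MGUS was -0.39 in place of -1.17. That of the monocyte-like share in WM against healthy was -2.1 in place of -2.83.

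DESeq2 called 139, 46 and 41 genes in monocyte-like cells for MGUS against healthy, WM against healthy and WM against MGUS, 34, 692 and 105 in B cell-like, 3, 99 and 1 in CD4 T-like, 24, 114 and 3 in CD8 T-like cells, and 1 and 81 in NK-like cells for MGUS and WM against healthy. Its overlap of the contrasts against healthy held 11 genes in monocyte-like, 32 in B cell-like, 3 in CD4 T-like, 19 in CD8 T-like and 1 in NK-like cells, against 0 with edgeR. With no filterByExpr filter the counts were 1 and 1 in monocyte-like cells (MGUS and WM against healthy), 56 in B cell-like cells (WM against MGUS), 1 and 4 in CD4 T-like cells (MGUS and WM against healthy), 2 in CD8 T-like cells (WM against MGUS) and 14, 154 and 13 in NK-like cells. With only genes of an average log2 CPM of at least 4 they were 2 in monocyte-like cells (WM against healthy), 225 and 2 in B cell-like cells (WM against healthy and against MGUS) and 0 in CD8 T-like cells (WM against MGUS). Upper-quartile normalization gave 3 in monocyte-like cells (WM against healthy).

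With the depth covariate the counts were 3 in monocyte-like cells (MGUS against healthy), 0 in CD8 T-like and 7 in NK-like cells (WM against healthy). With no doublets left out they were 2 in monocyte-like and 4 in CD4 T-like cells (WM against healthy). With only the groups compared they were 10 in monocyte-like cells (WM against healthy), 2 and 4 in B cell-like cells (MGUS against healthy and WM against MGUS), 3 in CD4 T-like cells (WM against healthy), 1, 1 and 0 in CD8 T-like cells and 24 in NK-like cells (WM against healthy). With class by highest marker score they were 11 in B cell-like cells (WM against MGUS), 1 in CD4 T-like, 8 in CD8 T-like and 0 in NK-like cells (WM against healthy) and 0 in CD8 T-like cells (WM against MGUS). At most 8% mitochondrial UMIs left 4 in CD4 T-like cells, at least 1500 UMIs left 12 in CD8 T-like cells and at least 50 cells left 4 in NK-like cells, each in WM against healthy. Without the libraries with over 10% of barcodes removed, they were 14 in B cell-like cells (WM against MGUS), 1 in CD4 T-like and 0 in CD8 T-like cells (WM against healthy) and 0 in CD8 T-like cells (WM against MGUS). With the unnamed T cell clusters as CD8 T-like both WM contrasts gave 0.

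The replicate number as a block does not pair libraries, as the donors differ: 3 of 13 number pairs in monocyte-like, 2 of 15 in B cell-like, 2 of 15 in CD4 T-like, 1 of 15 in CD8 T-like and 2 of 10 in NK-like cells correlated above 0.1. With that block the counts were 254 and 16 in B cell-like cells (WM against healthy and against MGUS), 2 in CD4 T-like cells (WM against healthy), 1 and 0 in CD8 T-like cells (MGUS and WM against healthy) and 0 in NK-like cells (WM against healthy).

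For shares, the mean percent scale gave differences of -17.5 and -19.0 for monocyte-like cells (MGUS and WM against healthy), 29.6 for B cell-like cells (WM against MGUS) and -1.27 for conventional dendritic cell-like cells (WM against healthy), all past the threshold, and 1.33 for B precursor-like and -0.0845 for plasmacytoid dendritic (pDC) cell-like cells (MGUS against healthy), both of the other sign. Class by marker score gave log2 differences of -0.468 for non-classical monocyte-like, 1.82 for B cell-like, 0.225 for plasma cell-like and 1.05 for pDC-like cells in WM against MGUS, 0.0445 for B precursor-like cells in MGUS against healthy and 1.30 for pDC-like cells in WM against healthy. The B cell-like share in WM against MGUS also passed at 1.94 with at most 8% mitochondrial UMIs (adjusted p = 0.0455) and at 1.93 without erythroid-like cells and unnamed clusters in the denominator (adjusted p = 0.0227). Without B and plasma cell-like cells in the denominator, signs turned for B precursor-like (0.160) and NK-like cells (0.198) in WM against MGUS and for CD4 T-like (0.347) and CD8 T-like cells (0.155) in WM against healthy. The CD8 T-like difference in WM against healthy was 0.0823 with the unnamed clusters, the pDC-like one in MGUS against healthy -0.411 with no doublets left out and -0.0402 without the libraries with over 10% removed, the plasma cell-like one in WM against MGUS 0.0807 without those libraries, and the erythroid-like one in MGUS against healthy -0.0120 with haemoglobin-rich barcodes.

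With each library left out in turn, monocyte-like counts ranged from 0 to 5 in MGUS against healthy (5 without MGUS 2, 3 without MGUS 6), 0 to 1 in WM against healthy (1 without WM 1, 2, 5 or 6) and 0 to 1 in WM against MGUS (1 without WM 2). B cell-like counts ranged from 184 to 510 in WM against healthy (246, 184, 194 and 198 without healthy 1, 2, 3 and 4, 510 without WM 6) and 14 to 59 in WM against MGUS (21 and 14 without MGUS 1 and 2, 59, 21, 21 and 16 without WM 1, 2, 3 and 4). CD4 T-like counts ranged from 0 to 1 in MGUS against healthy (1 without healthy 2) and 0 to 12 in WM against healthy (0, 2, 0 and 1 without healthy 1 to 4, 12, 1, 1 and 0 without WM 1, 2, 4 and 7). CD8 T-like counts ranged from 0 to 65 in WM against healthy (0 without any healthy library or WM 2, 5 or 7, 65 without WM 1) and 0 to 1 in WM against MGUS (0 without MGUS 1, 2, 3, 6 or 7 or WM 2 to 7). NK-like counts ranged from 0 to 41 in WM against healthy (0 without any healthy library or WM 2 or 7, 29, 41, 1 and 4 without WM 1, 3, 5 and 6).

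Shares whose sign or call turned on 1 library were, in WM against MGUS, non-classical monocyte-like (-0.602 to 0.813, -0.602 without MGUS 3), B cell-like (1.72 to 2.23, past the threshold at 2.23 without WM 1), B precursor-like (-1.21 to 0.0206, the highest without WM 2) and erythroid-like cells (-0.263 to 0.797, the lowest without MGUS 6). In the contrasts with healthy these were B precursor-like (-0.942 to 0.140, the highest without MGUS 6) and pDC-like cells in MGUS (-0.618 to 0.615, the lowest without healthy 4) and CD4 T-like cells in WM (-0.608 to 0.0336, the highest without WM 3). The share of B cell-like cells with atypical markers ranged from 0.780 to 1.18 in MGUS against healthy (1.18 without MGUS 1), -0.112 to 0.210 in WM against healthy (-0.112 without healthy 2) and -1.13 to -0.770 in WM against MGUS (-1.13 without MGUS 1). The light chain difference ranged from -0.273 to 0.111 in MGUS against healthy (0.111 without healthy 2) and 1.10 to 2.15 in WM against MGUS (2.15 without WM 7).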

Other observations

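Plasma cell-like cells differed in the antibody class they made. IGHM, the heavy chain of IgM, took 1.67% ± 2.29 (SD, n = 3) of heavy chain constant UMIs in healthy libraries, 74.7% ± 21 (n = 7) in MGUS and 74.9% ± 26.4 (n = 6) in WM. IGHA genes, of mucosal IgA, took 56.6% ± 6.62, 15.2% ± 13.5 and 7.54% ± 8.73, and IGHG genes, of IgG, took 40.1% ± 4.16, 9.99% ± 8.47 and 17.1% ± 21.8. The IGHM share was higher in all 7 MGUS libraries than the healthy median (exact p = 0.00833, adjusted p = 0.0286) and in all 6 WM libraries (exact p = 0.0119, adjusted p = 0.0286), and did not differ between WM and MGUS by more than the spread (exact p = 0.985). The p of both contrasts with healthy were the smallest that the group sizes allow. The IGHA share was lower in both patient groups (adjusted p = 0.0286 each), and the IGHG share in MGUS (adjusted p = 0.0286) but not past the threshold in WM (exact p = 0.119). All these shares are parts of 1 total, so a higher IGHM share lowers the others. The lower IGHA and IGHG shares are thus not separate findings and do not show fewer IgA or IgG cells.

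The test was written before this share was computed, but IGHM had by then been seen to be higher in B cell-like cells of WM. As a hypothesis, the MGUS donors may mostly carry IgM-type MGUS, the precursor of WM, rather than the more common IgG type: the value for WM against healthy was 0.0119 and MGUS resembled WM. The labels do not give the antibody class, and free RNA from other plasma cells in the same library would raise the dominant class, so a class per cell would be the next test.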
